A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

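The series compares RNA co-immunoprecipitated with zzMex67 with total RNA of Saccharomyces cerevisiae on 4 two-colour arrays. Per the labels, the precipitated RNA was in channel 2 on arrays 1 and 2 and in channel 1 on arrays 3 and 4. The titles carry 2 numeric codes whose meaning is not stated, labelled A (arrays 1 and 3) and B (arrays 2 and 4) here. Each code holds 1 array of each channel assignment. Slide and scan numbers in the titles were not used. Arrays were numbered in accession order, which pairs nothing.

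The deposited values are log10 ratios, 1 per probe and array. The base was read from the values, many of which equal log10 of a ratio of 2 whole numbers within 1.2e-09. The authors' steps before deposit (background correction, normalization and the rule by which probes lack a value) are not given in the sources used here. The deposited log10 ratios had array medians of -0.960, 0.462, -1.12 and -0.519, so the arrays were not centred on 0. The scale is settled by the values, the direction is likely precipitated over total RNA, from the wording of the labels, and remains unstated. Signal over background was not used here. The depth of an array can be described only by the probes with a ratio, 6.60%, 19.3%, 7.60% and 8.69% of 12800 on arrays 1 to 4.

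Probes were named through GEO's platform annotation, which can be old, checked through Entrez identifiers against the gene table of the reference: 11138 probes had 1 gene symbol, 0 had several and 1662 had none here, and 11128 identifiers matched. Repeated rows of a probe (2) were averaged with the first row of that probe. Of 5539 genes with a probe, 1750 had a ratio on at least 1 array. Ratios of the probes of a gene were averaged per array. For genes with 2 measured probes these correlated at r = 0.881, 0.753, 0.903 and 0.876 on arrays 1 to 4. Near-identical genes can share signal on a spotted array. No probe sequences and no genome were used, and no coordinates are given.

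Ratios were converted to log2. Features measured on at least 3 of 4 arrays, with both channel assignments present, were kept, and each array was centred on its median over them. The mean was tested against 0, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, at a Benjamini-Hochberg adjusted p under 0.05. The design had counted on the 2 channel assignments being balanced, and for most features they were not, because array 1 had no ratio. Error terms in the text are the SD over arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest, and statmod 1.5.0 for the random block.

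Before the data were examined, 21 gene lists were fixed, 9 of which had the 5 tested members needed for a list test. The design named camera with a correlation of 0.01. Because camera takes no missing values, its version for ranked statistics, cameraPR, was run on the moderated statistics with the same correlation. The estimated correlation and fry, which tests whether the genes of a list move one way on balance, used features complete on arrays 2 to 4. The genes named were those past the threshold, measured on all 4 arrays and on 1 side of the median on each, up to 12 per direction by size; the 3 largest called members of each list, or the 2 largest if none was called; and MEX67, MTR2 and YRA1. Unnamed probes were counted and not printed. Fisher's tests of the share of each list that was tested were chosen after the data were seen, as was the same comparison within blocks of 400 consecutive probes, an exact test on the summed hypergeometric counts with each gene placed by its first probe.

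The fit was tested on simulated ratios with the real missing values of the 596 features, 200 of them changed. With equal spread on the 4 arrays, 64% of the features changed by 1 log2 and 94% of those changed by 2 were recovered, and 2.99% of the calls were false. With 4 times the spread on array 1, 16% and 86% were recovered. A changed list was recovered by the list test in both cases. The simulated errors were independent between features and arrays, with no dye or position effect. Errors shared by nearby spots or between arrays were thus not simulated, and the share of false calls does not cover them.

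The alternatives fixed beforehand were no centring, scaling, quantile normalization, other limits on missing values, a term for the channel assignment, the title code as a random block or averaged, each array left out, a variance trend, stricter thresholds, ranks, and probes kept apart. For the lists they were other set tests and 1 member per A and B pair. A pseudocount did not apply to log ratios. Centring within blocks of probes, centring on features on all 4 arrays, leaving out array 1 with the other arrays complete, ranks over the arrays with a value, and the estimated correlation from arrays 2 to 4 were added after the data were seen.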

Results

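RNA bound to Mex67, the export receptor that carries mRNA through the nuclear pores of budding yeast, was measured against total RNA on 4 two-colour DNA arrays. RNA recovered with a tagged Mex67 (zzMex67) was hybridised together with total RNA on each array, so that each spot gave a ratio of the 2 RNA sources. All 4 arrays belonged to 1 group and no untagged or mock precipitation was analysed here. The precipitated RNA was in channel 2 on arrays 1 and 2 and in channel 1 on arrays 3 and 4. Most spots held no value: of 12800 probes, 845 had a ratio on array 1, 2467 on array 2, 973 on array 3 and 1112 on array 4. The number of arrays limits the precision of every value below, and nothing in the labels says whether the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

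The ratios are described as likely precipitated over total RNA. The labels name the quantity as a level of Mex67 binding, but they do not state the direction of the ratio. Arrays with opposite channel assignments correlated above 0, and by a rule fixed before the data were examined all 4 columns were then read as turned the same way. A dye effect specific to each spot, on ratios that had not been turned, would give the same positive correlations and was not separated from this reading. With arrays 3 and 4 turned against arrays 1 and 2 instead, 0 features passed in the fit described below (limma; 1 at an unadjusted p under 0.05), so that every call rests on this reading.

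Arrays 2, 3 and 4 ranked the transcripts alike, and array 1 did not. Across the features (genes, or single probes without a gene name) measured on both arrays of a pair, Pearson's r was 0.889 for arrays 3 and 4 (581 features), 0.824 for arrays 2 and 4 (742 features) and 0.756 for arrays 2 and 3 (646 features). Array 1 correlated with arrays 2, 3 and 4 at r = 0.127, 0.239 and 0.163, over 203, 92 and 106 features. Features are not independent replicates, so these 6 correlations describe the arrays and were not tested. How much of the agreement of arrays 2 to 4 rests on spot position was not tested either. Of the 566 features measured on all of arrays 2 to 4, 424 (74.9%) lay on the same side of the array median on each, where 25% would do so by chance.

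**Figure D1:**
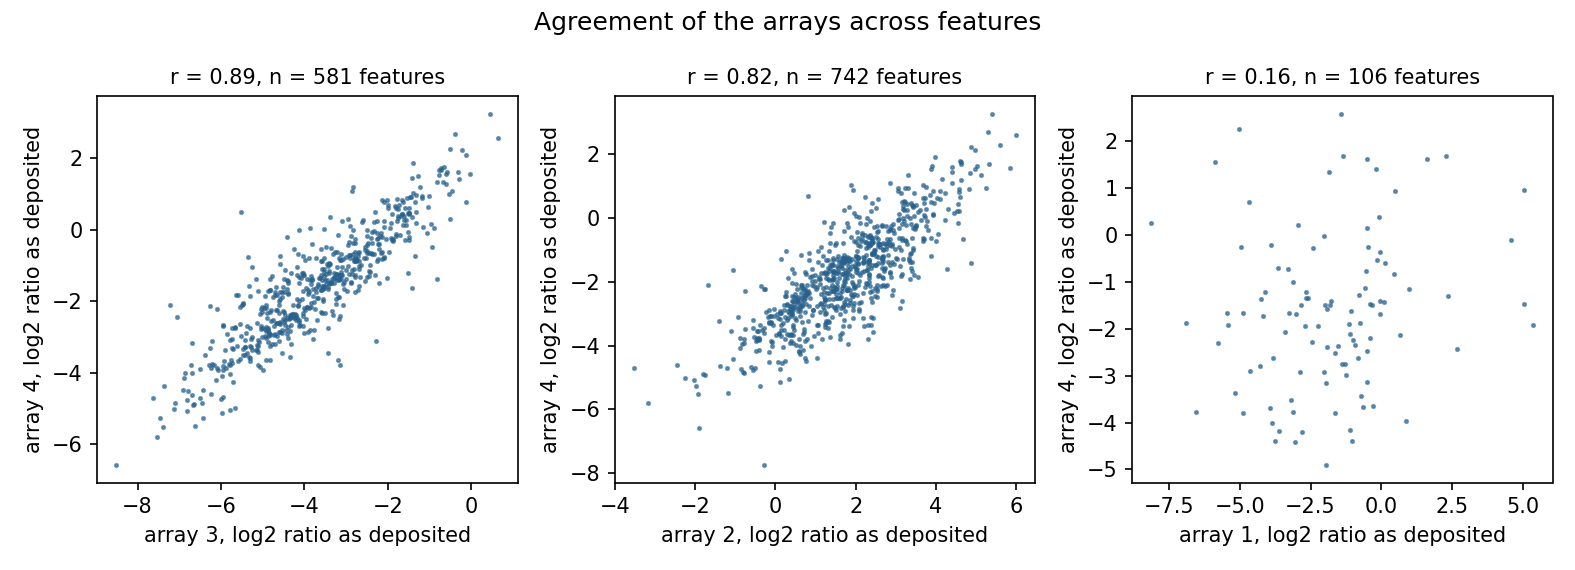
Log2 ratios as deposited, each point a feature measured on both arrays; the axes are the 2 arrays of a pair. Arrays 3 and 4 (r = 0.89) and arrays 2 and 4 (r = 0.82) follow one line, and arrays 1 and 4 (r = 0.16) form a cloud.

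The comparison implied by the design asks which transcripts were over- or under-represented among Mex67-bound RNA. Transcripts for RPL8B, a protein of the large ribosomal subunit, lay 10.2-fold above the array median (mean log2 3.35 ± 0.13, SD, n = 4), and those for CYC1, the main cytochrome c, lay 9.96-fold above it (log2 3.32 ± 0.61, SD, n = 4). RPL8A, paired with RPL8B by name, had 0.55 ± 2.67 (SD, n = 4) and was not called (limma, adjusted p = 0.663). At the other end, DBP2, an RNA helicase, lay 7.98-fold below the median (log2 -2.996 ± 1.13, SD, n = 4), and NAB3, an RNA-binding protein of transcription termination, 5.50-fold below (log2 -2.46 ± 1.62, SD, n = 4). Read as total over precipitated RNA, RPL8B would lie 10.2-fold and CYC1 9.96-fold below the median, DBP2 7.98-fold and NAB3 5.50-fold above it, and each direction below would turn. In all, 127 features lay above the array median and 148 below it among the 596 tested (498 named genes and 98 unnamed probes), by limma's moderated test with Benjamini-Hochberg adjustment, and 321 did not pass. Of these calls, 101 above and 117 below were named genes. The adjusted p was 0.00153 for RPL8B, 0.00311 for CYC1, 0.00540 for DBP2 and 0.0228 for NAB3. Centred within blocks of probes, as described below, the mean log2 was 2.07 for RPL8B, 2.45 for CYC1, -2.39 for DBP2 and -1.65 for NAB3. Without array 1, where it lay at -0.06, NAB3 had a mean of -3.26. The call of NAB3 ended without array 2 (adjusted p = 0.0722) or array 3 (adjusted p = 0.0664). It also ended in limma fits to features on all 4 arrays (adjusted p = 0.0679) or on at least 2 (adjusted p = 0.0580). The counts fell to 74 above and 81 below without array 4 and to 84 and 94 without array 3.

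Among the features above the median on each of the 4 arrays, the largest other means belonged to the following genes. RPS27B and RPS21B, of the small ribosomal subunit, had mean log2 ratios of 2.81 ± 0.76 and 1.83 ± 0.32 (SD, n = 4), and RPL40A, a fusion of ubiquitin and a ribosomal protein, 2.27 ± 0.57 (SD, n = 4). The alcohol dehydrogenase ADH1 had 2.59 ± 1.39 and the glyceraldehyde-3-phosphate dehydrogenase TDH1 2.46 ± 0.88 (SD, n = 4). DTD1, a deacylase of mischarged tRNA, had 1.97 ± 0.55, and the sphingoid base phosphatase YSR3 1.51 ± 0.30 (SD, n = 4). MTC6, YGR153W and the glutathione transferase GTO1 had means of 3.46 ± 2.31, 3.31 ± 1.90 and 2.34 ± 1.55 (SD, n = 4). On these 3 genes array 1 lay far from the other arrays, and without it the means were 2.31, 4.26 and 3.11. Centred within blocks they were 1.17, 3.92 and 3.09. ADH1 had 3.27 without array 1 and 1.31 centred within blocks, and GTO1 lost its call without array 2 (adjusted p = 0.0748) or array 3 (adjusted p = 0.0715). In a limma fit to features on all 4 arrays the calls of ADH1, MTC6, YGR153W and GTO1 ended (adjusted p = 0.0567, 0.0758, 0.0567 and 0.0860).

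Below the median on each of the 4 arrays lay MKC7, an aspartyl protease of the cell surface, at a mean log2 of -2.33 ± 1.11 and the asparaginase gene ASP3-1 at -2.16 ± 0.82 (SD, n = 4). HDA2, a subunit of a histone deacetylase, stood at -1.77 ± 0.69, the gamma-glutamyltransferase ECM38 at -1.25 ± 0.81 and MSF1, the mitochondrial phenylalanyl-tRNA synthetase, at -0.83 ± 0.54 (SD, n = 4). The calls of ECM38 and MSF1 ended in a limma fit to features on all 4 arrays (adjusted p = 0.0876 and 0.0951). They also ended with features on at least 2 arrays (limma, adjusted p = 0.0544 and 0.235). Of 11 features that met this rule below the median, 4 were unnamed probes, which lay in pairs of consecutive numbers. Unnamed probes were not averaged, and whether such a pair held 1 sequence was not checked. A sequence can thus count more than once among the 98 unnamed probes tested and in the calls.

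All of these positions are relative to the array median, which throughout is the median over the tested features with a ratio on that array. On array 1 it rested on 110 features, and the median over all probes with a ratio was lower, at log2 -3.19. Against the latter NAB3, at -1.94 as deposited on array 1, would lie above, so the side of a feature on array 1 depends on this choice. The medians removed were log2 -1.88, 1.79, -3.73 and -1.61 on arrays 1 to 4, and without centring 0 of the 596 features passed with limma, 52 of them at an unadjusted p under 0.05. Only 80 features had a ratio on all 4 arrays, 486 lacked array 1, and for those the channel assignments were unequal, so that a dye effect did not cancel in their mean.

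The genes for Mex67 and its partners gave little. MEX67 and YRA1, an adaptor that hands mRNA to Mex67, had no ratio on any array, and MTR2, which forms a dimer with Mex67, had a ratio on array 1 only. Of 38 mRNA export and nuclear mRNP genes with a probe, 3 were tested: NAB3 lay below the median, also when adjusted over the list alone, and the other two did not pass. GLE2, of the nuclear pore, had a mean log2 of 0.80 ± 0.98 (SD, n = 3). NUP1, also of the pore, had 0.49 ± 0.46 (SD, n = 3), and neither of the 2 pore genes tested passed. With 1 array left out GLE2 had 0.27 to 1.24 and NUP1 0.22 to 0.63.

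Ribosomal protein genes were over-represented among the transcripts with values and lay on both sides of the median. Of 132 with a probe, 42 (31.8%) were tested, against 8.99% of all genes (Fisher's exact test, two-sided, adjusted p = 1.0e-12, over 18 lists, chosen after the data were seen). The share of probes with a ratio differed between blocks of 400 consecutive probes, from 1.25% to 80.25% on array 2, and compared within blocks 13.4 of the 42 were expected (adjusted p = 4.3e-12). Both tests take genes as independent, and 14 A and B pairs had both genes tested, so their p-values can be too small. The share says which genes had ratios, by a rule that is not given, and nothing about Mex67 binding. Of the 42, 9 lay above, 9 below and 24 did not pass; adjusted over the list alone, 9 lay above and 8 below. RPL8B and RPP2A, an acidic protein of the ribosomal stalk, lay above at log2 3.35 ± 0.13 (SD, n = 4) and 2.87 ± 0.36 (SD, n = 3), and RPL2B lay below at -3.46 ± 0.36 (SD, n = 3). Of the genes paired with these by name, RPL8A, at 0.55 ± 2.67 (SD, n = 4), and RPL2A, at -1.20 ± 1.40 (SD, n = 3), did not pass. RPP2B lay below at -1.81 ± 0.14 (SD, n = 3). The list as a whole did not differ from the other features (camera, adjusted p = 0.742; adjusted p = 0.931 with an estimated correlation). Without array 1, 15 lay above and 11 below, and centred within blocks 6 and 6.

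Enzymes of glycolysis and fermentation also lay on both sides of the median. Of 27 with a probe, 13 (48.1%) were tested (Fisher's exact test, adjusted p = 1.2e-06; 8.1e-07 within blocks), 4 lay above, 4 below and 5 did not pass, with the same counts when adjusted over the list alone. ADH1 and TDH1 lay above, whereas CDC19, the main pyruvate kinase, stood at log2 -3.25 ± 0.91 and the aldolase FBA1 at -2.73 ± 0.39 (SD, n = 3). The list's median was 0.29, its mean -0.15 and its test pointed down (camera, adjusted p = 0.742); the mean was 0.06 without array 1 and -0.29 without array 4, and -0.32 centred within blocks. Centred within blocks, 2 lay above and 3 below.

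Of the 5 respiratory chain and ATP synthase genes tested, 3 lay above the median, 0 below and 2 did not pass, with the same counts when adjusted over the list alone. Beside CYC1, the complex III subunit QCR9 had a mean log2 of 2.55 ± 0.53 and the second cytochrome c gene CYC7 1.01 ± 0.55 (SD, n = 3). The call of CYC7 ended with the title code as a random block (adjusted p = 0.0538) or the arrays of a code averaged (adjusted p = 0.0779). This list came nearest to a difference from the other features, at an unadjusted camera p of 0.0206, and did not pass (adjusted p = 0.186; adjusted p = 0.931 with an estimated correlation).

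Cell wall genes were also frequent among the tested features (13 of 56, 23.2%; Fisher's exact test, adjusted p = 0.00656; 0.00362 within blocks) and also split: 3 lay above, 4 below and 6 did not pass, likewise over the list alone. The aspartyl protease YPS1 stood at log2 3.06 ± 0.26 (SD, n = 3) and the wall protein HSP150 at 1.49 ± 0.16 (SD, n = 4), while ECM33 stood at -3.26 ± 0.34 (SD, n = 3). The camera adjusted p was 0.976, with a median of -0.07 and a mean of 0.04 (0.01 to 0.06 with 1 array left out). Without array 1, 5 lay above and 4 below, and centred within blocks 2 and 2.

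Amino acid synthesis genes had 0 of 10 above, 3 below and 7 not past the threshold, and 2 below when adjusted over the list alone. LEU2, TRP2 and PRO3, of leucine, tryptophan and proline synthesis, stood at log2 -1.82 ± 0.66, -1.25 ± 0.22 and -0.94 ± 0.47 (SD, n = 3), and the camera adjusted p was 0.742. Of 5 translation factors, 2 lay above, the elongation factor eIF5A gene HYP2 at 1.77 ± 0.11 and the eIF2B subunit GCD6 at 1.60 ± 0.92 (SD, n = 3), also over the list alone, and 3 did not pass (camera, adjusted p = 0.742); the median was -0.62 and the mean 0.02, or 0.38, -0.04, -0.12 and -0.13 without arrays 1 to 4 and -0.25 centred within blocks. Of 5 chaperone genes, the Hsp70 gene SSA2 lay above at 2.98 ± 0.31 (SD, n = 3), also over the list alone, and 4 did not pass (camera, adjusted p = 0.742); the median was -0.06 and the mean 0.47, or 1.00, 0.22 and 0.28 without arrays 1, 3 and 4. Of 5 genes for translocation and glycosylation, 2 lay above, also over the list alone, and 3 did not pass (camera, adjusted p = 0.742). Both code for oligosaccharyltransferase subunits, SWP1 at 2.58 ± 0.66 and STT3 at 1.71 ± 0.82 (SD, n = 3). The list of intron-containing genes outside the ribosomal proteins was written out by name, not taken from an annotation, and need not be complete. Of 7 genes tested from it, QCR9 and TAF14, a subunit of TFIID and other complexes, lay above, the latter at 0.74 ± 0.08 (SD, n = 3). SRC1, an inner nuclear membrane protein, lay below at -1.96 ± 0.53 (SD, n = 3), and 4 did not pass (camera, adjusted p = 0.742). Adjusted over the list alone, 1 lay above and 1 below. With an estimated correlation the adjusted p was 0.931 for each of these lists.

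The remaining lists had under 5 genes tested and no list test. Of 2 genes tested whose names matched the mitochondrial ribosomal list, MRPS18 lay above at log2 2.85 ± 0.52 (SD, n = 3). Over the list alone MRPS18 and MRP8 both did, the latter at 1.25 ± 0.93 (SD, n = 3). Whether MRP8 codes for a mitochondrial ribosomal protein was not checked. Of 2 TCA cycle genes MDH1, a malate dehydrogenase, lay below at -1.84 ± 0.31 (SD, n = 3), and over the list alone 1 lay above and 1 below. Of 4 ergosterol genes the HMG-CoA synthase gene ERG13 lay below at -1.80 ± 0.30 (SD, n = 3), and of 4 ribosome biogenesis genes DBP2 lay below, both also over the list alone. The proteasome gene RPN2, at 0.15 ± 0.56, and the histone H3 gene HHT2, at 0.93 ± 1.26 (SD, n = 3), did not pass. Of 11 mating genes with a probe, 0 were tested, and the lists of mitochondrially encoded transcripts, noncoding RNAs and Ty elements had no named probe here.

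**Figure D2:**
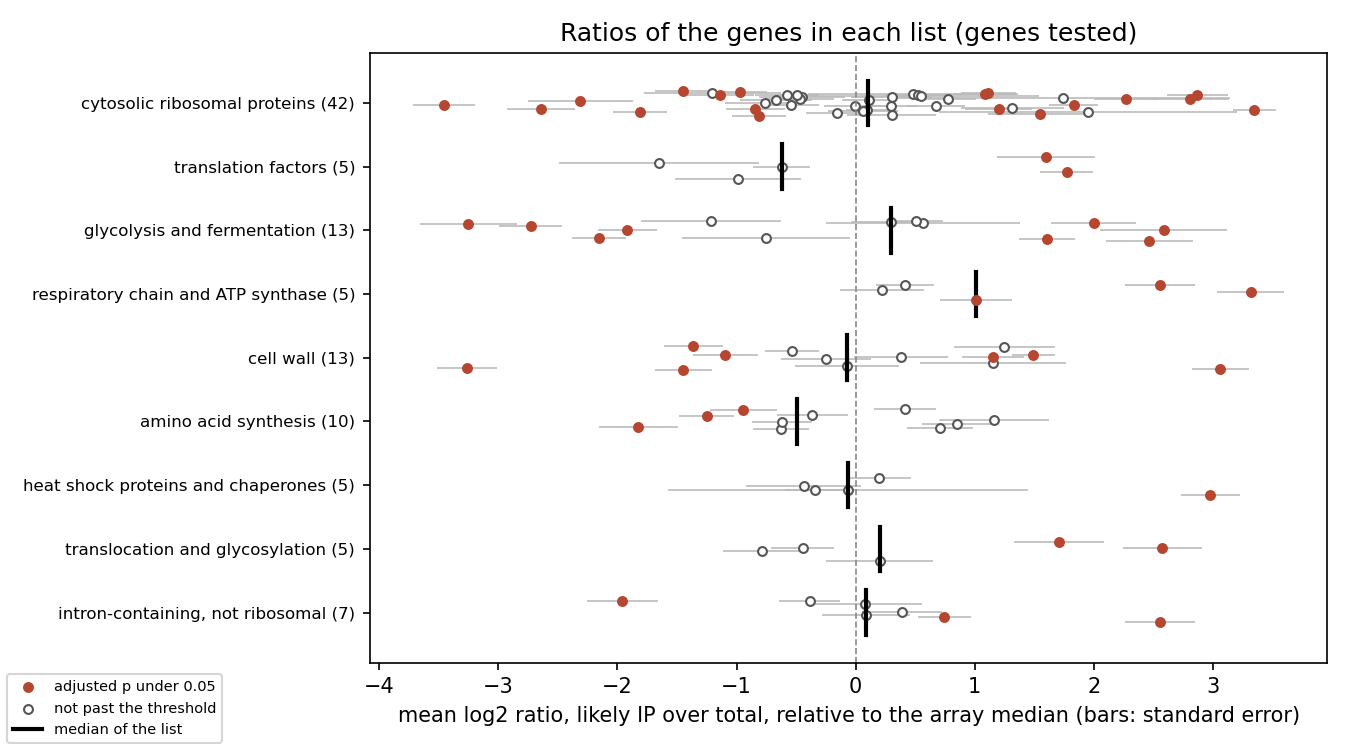
Mean log2 ratio of each tested gene relative to the array median, by list, with the standard error as a bar; filled points passed an adjusted p of 0.05, open points did not, and the thick line is the list's median. The 42 ribosomal protein genes spread from -3.46 to 3.35, and the 5 respiratory chain genes lie between 0.22 and 3.32.

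When ratios were centred within each block of 400 consecutive probes, an alternative chosen after the data were seen, 176 of the 275 calls were kept; among the genes named above, the calls of RPS27B, RPS21B, HDA2, ECM38, MSF1, MRPS18, HYP2, CYC7, HSP150, PRO3 and TAF14 ended, TAF14 at a mean of -0.03 ± 0.23 (SD, n = 3), and HHT2 passed. RPS21B and HSP150 kept most of their means, at 1.56 ± 1.30 and 1.29 ± 1.02 (SD, n = 4), and their calls ended as the spread between arrays widened (adjusted p = 0.0581 and 0.0562). The mean fell and the spread widened for RPS27B, to 1.5 ± 1.28 (SD, n = 4), and for MRPS18 and HYP2, to 1.24 ± 0.85 and 0.42 ± 0.37 (SD, n = 3). The mean moved towards 0 and the spread narrowed for HDA2 and ECM38, to -0.73 ± 0.40 and -0.65 ± 0.32 (SD, n = 4), and for CYC7 and PRO3, to 0.70 ± 0.49 and -0.37 ± 0.10 (SD, n = 3), and MSF1 had -0.60 ± 0.54 (SD, n = 4). Of those that held, RPL2B had -2.38, RPP2A 1.71, QCR9 1.78 and SSA2 1.63. The counts above became 2 of 5 for the respiratory chain, 1 of 5 for translation factors, 1 of 7 for intron-containing genes and 0 of 2 for the mitochondrial ribosomal list. Without array 3 or array 4 the calls of ECM38, MSF1, GCD6, CYC7, LEU2, PRO3, STT3 and TAF14 ended, without array 4 also that of TRP2, and without array 2 those of MSF1 and TAF14. With the title code as a random block the calls of MSF1, PRO3 and TAF14 ended beside that of CYC7 (adjusted p = 0.0529, 0.0558 and 0.0562), and with the arrays of a code averaged those of MSF1, PRO3, TAF14, ECM38 and TRP2 (adjusted p = 0.151, 0.0784, 0.130, 0.0612 and 0.0543). Without array 1, 2 amino acid synthesis genes lay above and 4 below, 2 chaperone genes above, 2 genes of the mitochondrial ribosomal list above, 2 ribosome biogenesis genes below, and 1 TCA cycle and 1 ergosterol gene above. Ratios of different genes on nearby spots were alike, with r = 0.705 on array 1 and 0.325, 0.485 and 0.463 on arrays 2, 3 and 4 for probes 2 numbers apart.

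**Figure D3:**
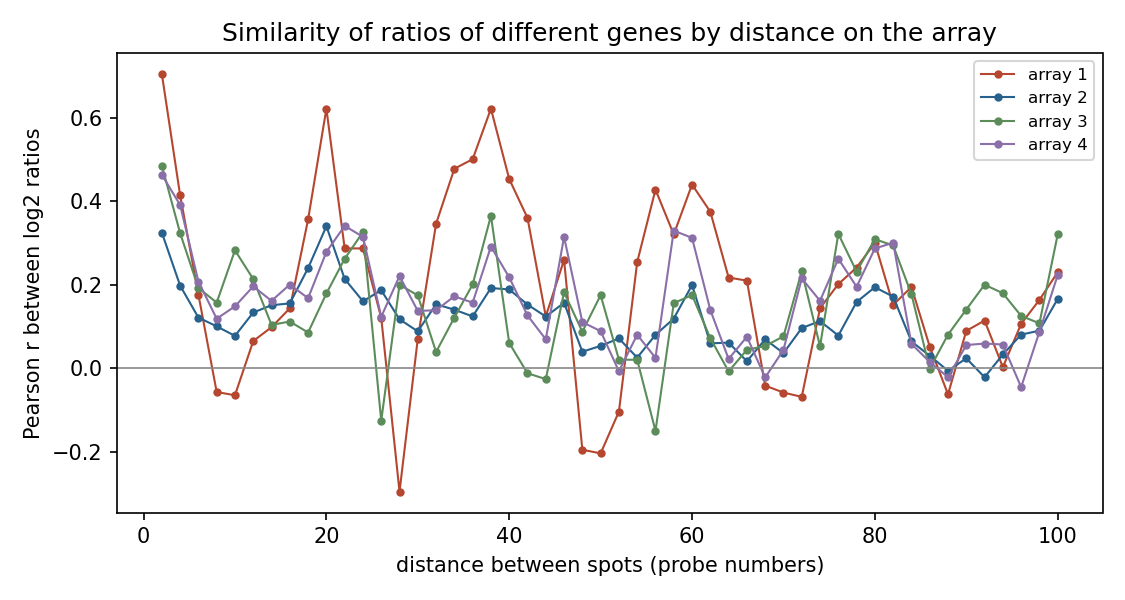
Pearson's r between the log2 ratios of different genes against the distance between their probe numbers, 1 line per array. Array 1 reaches 0.70 at a distance of 2 and 0.62 at 20, above the other three arrays at both distances.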

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

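In this part, the tests of local gradients on array 1, of the sign patterns and of array 1 by its smaller channel were chosen after their results had been seen, and the tests of the larger signals and of block-wide offsets before.

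Of 27 groups of 4 array values examined, 5 had 1 array far from the others, where chance gives about 1 in 20. Array 2 had 2467 probes with a ratio, against 845 to 1112 on the others. Array 1 had a mean correlation with the other arrays of 0.176, against 0.569 to 0.628. For MTC6 array 1 lay at log2 6.90, far above arrays 2 to 4, and for YGR153W and GTO1 it lay at 0.47 and 0.0264, far below them. Among the 80 features with 4 ratios, 23 had 1 array apart, array 1 each time, where about 4 are expected by chance.

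Array 1 thus stands apart from arrays 2 to 4, and no biological explanation was tested, since the labels give all 4 arrays as 1 group. Local gradients are a candidate explanation: ratios of different genes 20 probes apart correlated at 0.621 on array 1 (95% interval 0.562 to 0.675), against 0.179 to 0.340 on the others, a distance picked after a scan of distances. All intervals in this paragraph take probes, features or pairs of probes as independent. Ratios of probes of 1 gene and of nearby spots were alike, so the intervals are too narrow. Low signals and block-wide offsets, each as the whole cause, needed a correlation of at least 0.5 once removed, and the intervals stay under it. Neither is known to have been removed. The signals were read from fractions in lowest terms, which need not be the intensities. On array 1 the median block of 400 probes had ratios at 1.375% of them, so its centre rested on few values. The tests thus do not settle either cause. On array 1, 68.6% of the ratios could be read as ratios of 2 whole numbers (within 1.2e-09 on the log10 scale) of which the smaller was at most 40, against 1.64% to 5.39% on the others. The Spearman correlation with the mean of arrays 2 to 4 was 0.146 (-0.025 to 0.317) with the larger signals, 2 of whose 132 probes had so low a channel, and 0.115 (-0.081 to 0.3007) with the smaller. By the smaller channel it was -0.006 (-0.210 to 0.188) up to 40 and 0.163 (0.000 to 0.313) above, so that low signals as a part of the cause stay open. Block centring moved the mean correlation from 0.176 to 0.0997 (-0.116 to 0.292, a bootstrap adopted after the value was known; up to 0.374 per pair of arrays, the interval used first). The stricter bound of 0.3, set beforehand for excluding either, is crossed by the interval of the larger signals and by that per pair of arrays.

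The count of 275 features was set against the 8 sign patterns of the 4 arrays. The pattern used gave the highest count, 1 pattern of the 8, and the highest of the other patterns, in which array 1 alone was turned against the rest, gave 268. Too few patterns exist for a share under 0.05. Of the 596 features tested, 486 had no ratio on array 1.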

How the results depend on the processing

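The alternatives added after the data were seen were block centring, centring on features on all 4 arrays, array 1 left out with the others complete, ranks over the arrays with a value, and the estimated correlation from arrays 2 to 4. The counts of 127 features above and 148 below stayed within 1.5 times under scaling, quantile normalization, a channel term, both treatments of the title code, a variance trend, a log2 minimum of 1, at least 2 arrays, block centring, centring on features on all 4 arrays and array 1 left out. Without centring they were 0 and 0. Centring removes medians over the tested features of log2 -3.73 to 1.79. With features on all 4 arrays the counts were 9 and 7 of 80, where the fit reported called 15 and 12 of the same 80. The moderated test draws the spread of each feature towards that of all features fitted. In the fit reported 486 of the 596 lacked array 1, so the p-values of features with array 1 can be too small there. How far this accounts for the difference was not tested. An adjusted p under 0.01 gave 66 and 66, and probes kept apart 194 above and 210 below of 822. The top and bottom 20% held 6 and 2 features on all 4 arrays (0.128 each by chance) and 63 and 63 on the arrays with a value (4.26 each by chance). Leaving out 1 array gave 74 to 166 above and 81 to 176 below. The highest counts came without array 1, while leaving out array 3 gave 84 and 94 and array 4 gave 74 and 81. No list passed in the fit reported, and 1 did with features on all 4 arrays (ribosomal proteins, mean 1.00, adjusted p = 0.00816, the 1 list tested; 0.107 with an estimated correlation), and 3 with fry (translation factors, respiratory chain and chaperones, adjusted p = 0.0368, 0.0185 and 0.0298); the cause was not tested.

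The lists whose test changed direction all had an adjusted p above 0.8. With block centring the means of the intron-containing genes and the translation factors changed sign, to -0.0302 and -0.254, the test of the latter not turning, while the means of the ribosomal proteins (0.0226) and cell wall genes (0.107) kept theirs and only the test turned. The translation factors' mean of 0.0221 was also below 0 with a channel term (-0.0190), and -0.131 to 0.380 with 1 array left out. Glycolysis had 0.0093 with array 1 left out, with an estimated correlation and with fry, and -0.292 to 0.0568 with 1 array left out. Cell wall genes had 0.0358 by ranks, 0.0594 with fry and 0.00915 to 0.0581 with 1 array left out, where the test and not the mean changed sign. Of the 49 named features, 6 reversed without centring, CYC7 (-0.17), RPN2 (-1.03), GLE2 (-0.38), NUP1 (-0.69), HHT2 (-0.25) and TAF14 (-0.44), and all 45 calls among the 49 were lost. TAF14 reversed with block centring (-0.0263), and RPN2 without array 2 (-0.13 to 0.42 over the arrays left out); the cause was not tested. Named calls lost numbered 13 with block centring, where 1 was gained, 8 of 24 with features on all 4 arrays, 4 with a channel term and the same 4 with the title code as a random block (CYC7, MSF1, PRO3 and TAF14), 6 with it averaged (also ECM38 and TRP2), 7 with at least 2 arrays, 3 with a variance trend, 3 with centring on features on all 4 arrays, 0 with scaling, quantile normalization or array 1 left out, and 4, 11 and 10 without arrays 2, 3 and 4. The channel term passed for 0 of 596 features with limma, 42 at an unadjusted p under 0.05. The shares of lists tested, compared within blocks (also added later), stayed on their side of the threshold; relative to expectation histones went from 1.01 to 0.567 and intron-containing genes from 0.779 to 1.03, neither past it. No paired analysis was possible because there is 1 group.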

Other observations

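In this part, the test of chromosomal neighbours was chosen before its result was seen; the tests of slide-specific background and the tests of the hexose transporters were chosen after.

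Genes for hexose transporters, which carry glucose into the cell, were not among the lists fixed beforehand. Of 17 with a probe, 9 were tested, 7 lay above the array median and 0 below. HXT3 had a mean log2 of 3.50 ± 0.29, HXT1 2.16 ± 0.08, HXT10 2.05 ± 0.36, HXT5 1.97 ± 0.35 and HXT7 1.89 ± 0.23 (SD, n = 3). HXT12 and HXT4 also passed, at 1.20 ± 0.21 and 0.99 ± 0.41, and HXT6 and HXT9, at 0.91 ± 0.51 and -0.11 ± 0.50 (SD, n = 3), did not. None of the 9 had a ratio on array 1.

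The family was picked because HXT1, HXT3 and HXT10 were seen among the highest ratios, so only the 6 other members bear on it. Their mean was 1.14, as high as in a share of 0.0208 of 10000 random lists of 6 tested features, which argues against chance among the features with values. After block centring the share was 0.0060, against offsets of whole blocks as the whole cause for the 6 as a set, but single members moved both ways and 4 of the 9 passed. The means of HXT10 and HXT5 fell to 0.70 ± 0.06 and 0.63 ± 0.26, which ended their calls, so that for these genes offsets stay open. HXT4, at 1.07 ± 0.65, kept its mean and lost its call as the spread widened (adjusted p = 0.0616), and HXT7 and HXT12 rose to 2.96 ± 0.46 and 2.00 ± 0.09 (SD, n = 3). Without centring the mean of the 6 was -0.04, and of the 9 members 6 lay above 0 and 3 below. The shares are too low to the extent that members share signal or lie on nearby spots, and how many other families would have caught the eye was not counted. Cross-hybridisation between these similar genes was not tested, and no biological explanation was tested; with the ratio turned the family would lie below the median.

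On arrays 2 to 4, ratios of different genes on nearby spots were alike. A background that differs between slides, as the whole cause, is argued against by the mean correlation between arrays, 0.349 for probes 2 numbers apart, with intervals of the 3 pairs of arrays from 0.190 upwards. This rests on genes of 1 chromosome (0.357, from 0.158 upwards), and for genes on different chromosomes, at 0.125 (-0.178 to 0.483), such a background stays open. Chromosomal neighbours printed side by side stay open: for probes of genes on different chromosomes the mean correlation within arrays was 0.168, and the intervals of the 3 arrays ran from -0.239 to 0.587. The intervals take pairs of probes as independent and are too narrow, so the case against a background that differs between slides rests on the correlations themselves. Block centring lowered the means of HYP2, SSA2, HXT10 and HXT5 alike, from 1.77, 2.98, 2.05 and 1.97 to 0.42, 1.63, 0.70 and 0.63. HXT7 moved the other way, from 1.89 to 2.96. Offsets of blocks thus did not average out over arrays 2 to 4. Whether they came from a spot position effect shared by the slides was not tested, and no biological explanation was tested.

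Ribosomal protein genes whose names differ only in a final A or B were paired by name, and whether the members of a pair code for the same protein was not checked. The 14 pairs with both genes tested had a median absolute log2 difference of 1.21, against 1.31 for random pairings of the same genes, and 37.1% of 10000 random pairings were as low. In 1 pair the 2 genes were called on opposite sides, RPP2A at 2.87 and RPP2B at -1.81, a pair chosen after its values were seen.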
